A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

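The series holds 12 RNA-seq libraries of the budding yeast Saccharomyces cerevisiae, 1 for each of 6 strains at each of 2 points of a fermentation. The strains were the laboratory strain S288c, the commercial wine strain EC1118 and 4 isolates from vineyards, P283, R008, R103 and P301. Per the labels' protocols, each strain fermented MS300, a synthetic must that imitates white grape juice, in a bioreactor, and cells were taken when 6 g/l of CO2 had been released (middle of exponential growth) and when 45 g/l had been released (mid-fermentation, at the start of the stationary phase). Total RNA was depleted of ribosomal RNA, decapped, freed of DNA and made into libraries with a SOLiD 4 whole-transcriptome kit, per the labels' protocols. Strain P283 has another number in its own free-text description and was called by the name in its title and strain label.

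The authors deposited a single table of RPKM values (read numbers scaled to the length of the gene and to the mapped reads of the library) with 1 column per library, per the file headers. The genome build was sacCer2, version 2, per the submitters' processing notes. The aligner, the counting program, the annotation release, the use of strand and the treatment of reads that match several places are not given in the sources used here. RPKM divide by a library's total, so abundant transcripts lower the values of all others, and a gene whose sequence differs between a strain and the reference can lose reads. Depth is unknown. It was looked for by testing whether RPKM times gene length came in whole multiples of 1 read. At the best of many steps tried, 35.0% to 47.5% of low values per library lay within 0.1 of a whole multiple. At a step fixed in advance 20% would by chance, and the best of many can exceed that by chance alone. No counts were recovered and no counting interval could be given. No count model was used.

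Of 6697 lines in the table, 3 were exact copies, 3 systematic names had lines with conflicting values and were left out, and 1 line named no gene (up to 0.365% of the summed RPKM, in S288c at 45 g/l). This left 6681 genes, of which 6003 matched a locus tag of the reference gene table for a later assembly. That table was used for names and neighbours only, because 26.0% of the start positions were equal in both; positions in the text are the coding start and end that the authors' table gives. Near-identical copies were found by searching the 6027 coding sequences of that later assembly against each other with blastn 2.17.0 (at least 95% identity over at least 50% of the length), which gave 314 genes with a copy. A further 1048 genes overlap a gene on the opposite strand, and reads of such pairs cannot be told apart without strand.

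Values were divided by a median-ratio factor per library, from the 4909 genes with at least 1 RPKM in every library (factors 0.807 to 1.28), and are called scaled RPKM. Tests ran on log2(scaled RPKM + 1) in limma 3.58.1 under R 4.3.3, with a mean-variance trend, for the 5944 genes with a mean of at least 1 RPKM. A fold change on this scale understates the change of low genes. A call is a Benjamini-Hochberg adjusted p under 0.05, two-sided. The phase effect was fitted over all 12 libraries with the strain as a block, so its spread is that of the response between strains. Each lone strain, S288c or EC1118, was compared with the 4 vineyard strains on the mean of its 2 libraries, and separately on the difference between its 2 libraries; the spread came from the vineyard strains (3 residual degrees of freedom), and the lone strain was assumed to vary like them. A strain effect over all 6 strains was tested with a moderated F test with the phase in the model, where the 2 phases stand in for repeats. Both libraries of a strain may come from 1 culture, so differences between cultures of a strain are not in any of these spreads. Within a strain there was 1 library per phase and no test; genes were counted at an absolute log2 ratio of at least 1.

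Strain numbers pair the libraries, since both libraries of a number come from the same strain. The deviations of a strain's 2 libraries from their phase means correlated at 0.46 to 0.71 across genes, and at −0.08 to 0.45 without the genes listed at 0. In the latter case some exponential libraries correlated more with another strain's mid-fermentation library than with their own. This held for P283 (0.03 with its own, 0.21 with another), R008 (−0.08 and 0.11) and R103 (0.18 and 0.21).

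Gene lists (41, from pathways and complexes of yeast) were written before the data were examined. The 38 with at least 5 tested members went through limma's camera with a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. The list meant for Ty elements was built from gene descriptions and caught mainly host genes whose descriptions mention Ty: of its 39 members 3 are retrotransposon reading frames. The retrotransposon family was therefore taken as the 93 reading frames that the authors' table describes as Gag or Gag-Pol of a Ty element, a change made after the data were seen.

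Genes named in the text follow a rule fixed at the same time as the lists. For the phase, these are the 6 risen and 6 fallen genes with the largest change among those called and moving the same way in 6 strains, and the 2 members of each list with the smallest p. For S288c and EC1118, these are the 6 higher and 6 lower genes with the largest difference among those called and on the same side in both phases. For the response contrasts, these are the 4 higher and 4 lower called genes, or the 3 with the smallest p where none was called. For the strain effect, these are the 2 genes per strain with the largest difference from the other 5. A fixed list of 25 genes known to vary between wine and laboratory yeasts was always included. Members of the seripauperin, retrotransposon and Y′ helicase families were given as families, apart from those named in the response contrasts. Other genes with near-identical copies were named singly. The rule was run once more without the genes listed at 0 in both libraries of a strain, an alternative chosen after seeing the data.

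Other alternatives were RPKM as deposited, quantile normalization, factors computed without ribosomal protein genes, pseudocounts of 0.1 and 5, no filter and a mean of at least 10 RPKM, robust empirical Bayes, no strain block, vineyard strains only, 1 phase only, S288c against the other 5 strains, and leaving out each strain. A list of 4 alpha-specific, 10 haploid-specific and 7 a-specific mating genes, 15 targets of HAP1 and 148 essential genes were written after the data had been seen, for tests in the closing section.

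The fits were tested on simulated data with the spread of the 5419 genes not listed at 0 in any strain, with 200 genes changed, 50 at each of 4 fold sizes. The phase fit recovered 42% of genes changed 2-fold, 94% at 4-fold, 98% at 8-fold and 100% at 32-fold, with 14 unchanged genes among 181 called. The S288c contrast recovered 0%, 64%, 78% and 98% at these sizes, and the EC1118 contrast 6%, 60%, 76% and 96%. The response contrast of S288c recovered 0%, 2%, 10% and 58%, and that of EC1118 0%, 2%, 4% and 68%. The strain effect test recovered 0%, 22%, 58% and 92%. Figures were drawn with matplotlib 3.10.9.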

Results

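Transcript levels were measured in 12 libraries from 6 strains of Saccharomyces cerevisiae fermenting a synthetic grape must, 1 library per strain at 6 g/l of released CO2 (exponential phase) and 1 at 45 g/l (mid-fermentation). The strains were 1 laboratory strain (S288c), 1 commercial wine strain (EC1118) and 4 vineyard isolates (P283, R008, R103 and P301), so each phase had 6 strains as its replicates and a strain had no replicate within a phase. The median gene had 16.5 to 30.2 RPKM, depending on the library, and the 10 most abundant genes held 13.1% to 23.4% of the summed RPKM. The number of reads behind these values is unknown. Between 442 and 927 of the 6681 genes were listed at 0 in a library.

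Many of the zeros covered both libraries of a strain for genes that were abundant in the other strains. TDH1, a glyceraldehyde-3-phosphate dehydrogenase of glycolysis, was listed at 0 in both libraries of P283 and had 6692 to 32058 scaled RPKM in the other 10. OLE1, the fatty acid desaturase, was listed at 0 in the same libraries and had 4804 to 26974 elsewhere. In P283 186 genes, in R103 175, in R008 119, in P301 89 and in S288c 17 were listed at 0 in both libraries of the strain while their mean in the rest was at least 10 RPKM, and EC1118 lay between P301 and R008. A near-identical copy was found for 82.4% of these genes in S288c, 78.7% in P301, 64.7% in R008, 59.2% in EC1118, 48.6% in R103 and 45.7% in P283. Of 4897 genes with a mean of at least 10 RPKM over all libraries, 333 were listed at 0 in both libraries of some strain, and 31.5% of these had a near-identical copy in the genome, against 1.07% of the rest. A zero is given here only as a listed value. Comparisons of single genes between strains are given with and without these genes, and those of gene lists mainly with them.

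**Figure D1:**
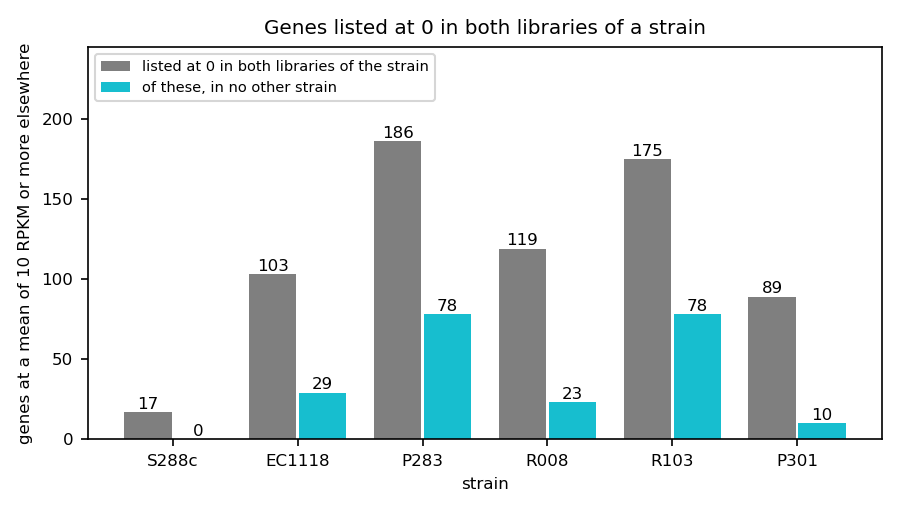
Number of genes (y axis) listed at 0 RPKM in both libraries of each strain (x axis) although their mean in the other strains was at least 10 RPKM, with grey bars for all such genes and turquoise bars for those listed at 0 in no other strain. P283 and R103 have the most, 186 and 175, of which 78 each are at 0 in that strain alone, and S288c has 17, of which 0 are at 0 in S288c alone.

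The first comparison asked which genes change between exponential growth and mid-fermentation over all strains. The gene lists of trehalose and glycogen, oxidative stress, respiration and beta-oxidation were called upward in camera, and those of ribosomal proteins, amino acid and purine synthesis and sulfur assimilation downward. With a correlation between genes estimated from the data, camera called 0 lists, and 9 had an unadjusted p under 0.05. SIP18, a stress-induced hydrophilin, showed the largest rise among the genes moving one way in 6 of 6 strains, from 40.2 ± 35.8 to 6412 ± 4153 scaled RPKM (SD, n = 6 strains), a log2 change of 7.35 ± 0.57 (SE, limma, adjusted p = 1.54e-05). PHO3, an acid phosphatase that acts on thiamine phosphates, showed the largest fall, from 712 ± 384 to 25.7 ± 11.4 scaled RPKM, a log2 change of −4.67 ± 0.26 (adjusted p = 2.83e-06). Of 5944 genes tested, 2891 changed, 1556 of them upward and 1335 downward.

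The other genes with the largest rises were heat and stress genes or genes of stationary-phase and spore-wall function. HSP30, a plasma membrane heat shock protein (YCR021C, chromosome 3, 156105 to 157103), rose by 6.83 ± 0.36 on the log2 scale, from 16.4 ± 12.3 to 1808 ± 929 scaled RPKM (SD, n = 6). HSP26, a small heat shock chaperone (YBR072W, chromosome 2, 382030 to 382674), went from 252 ± 182 to 14002 ± 2857 scaled RPKM, a log2 rise of 6.23 ± 0.46. SPS100, a spore wall protein (YHR139C, chromosome 8, 378222 to 379202), rose by 6.70 ± 0.28. SPG1, needed in stationary phase at high temperature (YGR236C, chromosome 7, 962534 to 962821), rose by 6.31 ± 0.25. DDR2, a protein induced by many stresses (YOL052C-A, chromosome 15, 231569 to 231754), rose by 6.17 ± 0.26. SIP18 itself (YMR175W) lies on chromosome 13 at 611015 to 611254. Adjusted p-values of these genes ran from 9.06e-07 to 1.54e-05, and each rose in 6 of 6 strains.

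After PHO3 (YBR092C, chromosome 2, 427698 to 429101), the largest fall was that of the ribosomal protein gene RPL9A (YGL147C, chromosome 7, 227759 to 228334), from 3802 ± 3107 to 117 ± 40.8 scaled RPKM (SD, n = 6), a log2 change of −4.61 ± 0.55. HXK2, the main hexokinase on glucose (YGL253W, chromosome 7, 23935 to 25395), went from 1745 ± 480 to 105 ± 73.7 scaled RPKM, a log2 change of −4.22 ± 0.30. MET3, the ATP sulfurylase that opens sulfate assimilation (YJR010W, chromosome 10, 456232 to 457767), went from 2459 ± 1864 to 110 ± 34.1 scaled RPKM, a log2 change of −4.12 ± 0.42. SRL1, a cell wall mannoprotein gene (YOR247W, chromosome 15, 797677 to 798309), had a log2 change of −4.57 ± 0.32. TOS11 (YOR248W, 798013 to 798315) overlaps SRL1, so that their reads cannot be told apart, and had a log2 change of −4.60 ± 0.34. Adjusted p-values ran from 2.83e-06 for PHO3 to 0.000137 for RPL9A, and each of these genes fell in 6 of 6 strains.

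Lists of growth functions were called downward. Of 138 ribosomal protein genes, 123 fell and 15 did not pass the threshold (128 fell and 1 rose when adjusted over the list alone), with a median log2 change of −2.08 (camera, adjusted p = 2.32e-25, and adjusted p = 0.294 with an estimated correlation). RPS2 went from 6464 ± 2848 to 616 ± 195 scaled RPKM (SD, n = 6), and the median of the list was lower in 6 of 6 strains, from −1.22 in P283 to −3.59 in R008. Of 71 ribosome biogenesis genes, 16 fell and 3 rose (11 and 2 adjusted over the list alone), with a median of −0.43 (adjusted p = 0.0104, and adjusted p = 0.615 with an estimated correlation). NOP56, a core protein of snoRNA particles, had a log2 change of −2.23 ± 0.31, although it overlaps another gene. The median of that list was 1.00 in P283 and −0.21 to −0.99 in the other 5 strains. Of 39 cell cycle and replication genes, 17 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.201 with an estimated correlation). The mitotic cyclin gene CLB2 went from 90.2 ± 49.4 to 4.72 ± 1.22 scaled RPKM. Of 10 histone genes, 4 fell, also adjusted over the list alone, with HTA2 at a log2 change of −1.76 ± 0.27 (adjusted p = 0.0209, and adjusted p = 0.402 with an estimated correlation). Of 34 proteasome genes, 16 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.201 with an estimated correlation). The riser was RPN4, the transcription factor of proteasome genes, at 2.14 ± 0.24.

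Lists of biosynthesis were called downward as well. Of 58 amino acid biosynthesis genes, 47 fell and 4 rose (48 and 4 adjusted over the list alone), with a median of −1.42 (adjusted p = 4.54e-13, and adjusted p = 0.194 with an estimated correlation). ASN1, an asparagine synthetase, went from 1166 ± 655 to 102 ± 43.4 scaled RPKM (SD, n = 6). Of 21 purine biosynthesis genes, 20 fell, also adjusted over the list alone, with SHM2, the cytosolic serine hydroxymethyltransferase, at −3.05 ± 0.30 (adjusted p = 6.09e-08, and adjusted p = 0.261 with an estimated correlation). Of 27 sulfur assimilation genes, 14 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.00126, and adjusted p = 0.458 with an estimated correlation). Their median was lower in 5 strains, down to −2.49 in P283, and was 0.21 in S288c. Of 25 ergosterol genes, 14 fell (16 adjusted over the list alone), with ERG13, the HMG-CoA synthase, at −1.52 ± 0.26 (adjusted p = 0.000376, and adjusted p = 0.39 with an estimated correlation). Of 23 thiamine and pyridoxine genes, 9 fell and 2 rose, also adjusted over the list alone, with THI20 at −3.21 ± 0.33 (adjusted p = 0.0419, and adjusted p = 0.536 with an estimated correlation). Of 23 genes of the anaerobic and hypoxic list, 11 fell and 5 rose, also adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.351 with an estimated correlation). TIR3, a cell wall mannoprotein, had a log2 change of −2.46 ± 0.27, while CYC7, the hypoxic isoform of cytochrome c, rose by 4.97 ± 0.50.

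Genes of carbon use moved in both directions. Of 21 glycolysis and fermentation genes, 8 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of −0.63 (adjusted p = 0.0427, and adjusted p = 0.339 with an estimated correlation). PDC6, a minor pyruvate decarboxylase, rose from 0.943 ± 1.09 to 25 ± 13.5 scaled RPKM (SD, n = 6). Of 12 hexose transporter genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.201 with an estimated correlation). HXT4 went from 3.37 ± 1.87 to 166 ± 58.3 scaled RPKM, HXT2 from 9.67 ± 12 to 249 ± 131 and HXT3, a transporter known from wine fermentation, from 464 ± 111 to 2197 ± 228. Of 16 gluconeogenesis and glyoxylate genes, 14 rose, also adjusted over the list alone, among them ADR1, an activator of glucose-repressed genes, at 2.55 ± 0.20 (adjusted p = 6.02e-06, and adjusted p = 0.194 with an estimated correlation). Of 18 beta-oxidation genes, 15 rose and 1 fell, also adjusted over the list alone, with FOX2 at 4.09 ± 0.26 (adjusted p = 2.76e-05, and adjusted p = 0.283 with an estimated correlation). Of 48 respiration genes, 41 rose and 0 fell (44 and 1 adjusted over the list alone, adjusted p = 1.19e-09, and adjusted p = 0.261 with an estimated correlation). QCR8, a subunit of complex III, went from 166 ± 106 to 2877 ± 656 scaled RPKM. Of 16 maltose, sucrose and galactose genes, 5 rose (4 adjusted over the list alone), with GAL4 at 1.56 ± 0.28 (adjusted p = 0.0209, and adjusted p = 0.201 with an estimated correlation).

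Lists of storage and of several stress and recycling functions were called upward, while that of heat shock and chaperones was not (camera, adjusted p = 0.112). Of 18 trehalose and glycogen genes, 14 rose (14, with 1 fallen, adjusted over the list alone, adjusted p = 8.51e-05, and adjusted p = 0.39 with an estimated correlation). IGD1, an inhibitor of glycogen debranching, went from 9.48 ± 6.55 to 139 ± 49.6 scaled RPKM (SD, n = 6). Of 28 oxidative stress genes, 17 rose and 3 fell (20 and 5 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.453 with an estimated correlation), with GPX1, a glutathione peroxidase, at 4.30 ± 0.40 and GSH2, glutathione synthetase, at −2.38 ± 0.22. Of 17 osmotic and glycerol genes, 8 rose and 1 fell, also adjusted over the list alone, with GRE1, a hydrophilin like SIP18, at 4.25 ± 0.45 (adjusted p = 0.00456, and adjusted p = 0.194 with an estimated correlation). Of 37 autophagy genes, 24 rose and 1 fell, also adjusted over the list alone, with QNQ1 at 5.40 ± 0.32 (adjusted p = 1.5e-05, and adjusted p = 0.194 with an estimated correlation). Of 20 multidrug resistance genes, 11 rose, also adjusted over the list alone, with RSB1, a sphingoid base exporter, at 5.42 ± 0.55 (adjusted p = 0.0037, and adjusted p = 0.261 with an estimated correlation). Of 36 sporulation genes, 21 rose and 1 fell (23 and 1 adjusted over the list alone), with OSW2, a spore wall gene, at 3.19 ± 0.29 (adjusted p = 0.00012, and adjusted p = 0.194 with an estimated correlation).

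The lists of genes under nitrogen catabolite repression and of copper genes were called upward too. Of 32 genes under nitrogen catabolite repression, 13 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.458 with an estimated correlation). The proline permease gene PUT4 stood at 4.03 ± 0.39 and the ammonium permease gene MEP1 at 2.75 ± 0.21. The median of this list was 0.24 to 2.28 in 5 strains and −0.17 in P301. Of 9 copper genes, 6 rose, also adjusted over the list alone, with CUP2, the copper-responsive activator, at 1.65 ± 0.21, although it overlaps another gene (adjusted p = 0.0209, and adjusted p = 0.201 with an estimated correlation).

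The other 13 lists were not called, with camera adjusted p from 0.0725 to 0.874. Of 27 heat shock and chaperone genes, 11 rose and 3 fell, also adjusted over the list alone. Of 13 fatty acid synthesis genes, 4 rose and 6 fell (4 and 7 adjusted over the list alone), including the elongase genes SUR4 at −3.76 ± 0.31 and FEN1 at −2.57 ± 0.35. Of 23 iron regulon genes, 8 rose and 2 fell, with FIT2 at 2.87 ± 0.44. Of 10 zinc genes, 2 rose and 3 fell, with the zinc transporter gene ZRT1 at −2.05 ± 0.28. Of 19 phosphate genes, 5 rose and 5 fell, with PHM8 at 4.71 ± 0.56 and PHO5 at −2.61 ± 0.26. Of 25 genes of aroma esters and higher alcohols, 2 rose and 8 fell, with ARO8 at −2.40 ± 0.21. Of 10 acetaldehyde and acetate genes, 5 rose and 2 fell, with ALD4 at 3.51 ± 0.35. Of 17 seripauperin genes 5 rose, of 31 genes whose descriptions mention Ty elements 10 rose and 4 fell, and of 17 wine and laboratory candidates 4 rose and 2 fell. The counts of these last 8 lists were the same adjusted over the list alone. Of 24 mating genes, 8 rose and 1 fell (8 and 0 adjusted over the list alone). Of 6 biotin genes, 1 fell (0 adjusted over the list alone in limma, and 1 at an unadjusted p under 0.05). It was BIO2, with a log2 change of −0.84 ± 0.27 (adjusted p = 0.0244), a call lost without S288c (−0.76), EC1118 (−0.82), R008 (−0.82) or R103 (−0.68), with RPKM as deposited, under quantile normalization, without the strain block and in the vineyard strains only. The 9 flocculation and adhesion genes had 2 risen members, also adjusted over the list alone, with a median of −0.02, a mean of 0.05 and a test in the upward direction that did not pass. Of the Y′ helicase genes, 3 could be tested and 0 changed in limma, with 0 at an unadjusted p under 0.05. The list of mitochondrially encoded genes matched 0 of the genes kept and that of ribosomal RNA named 0, so these RNAs were not analysed here.

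**Figure D2:**
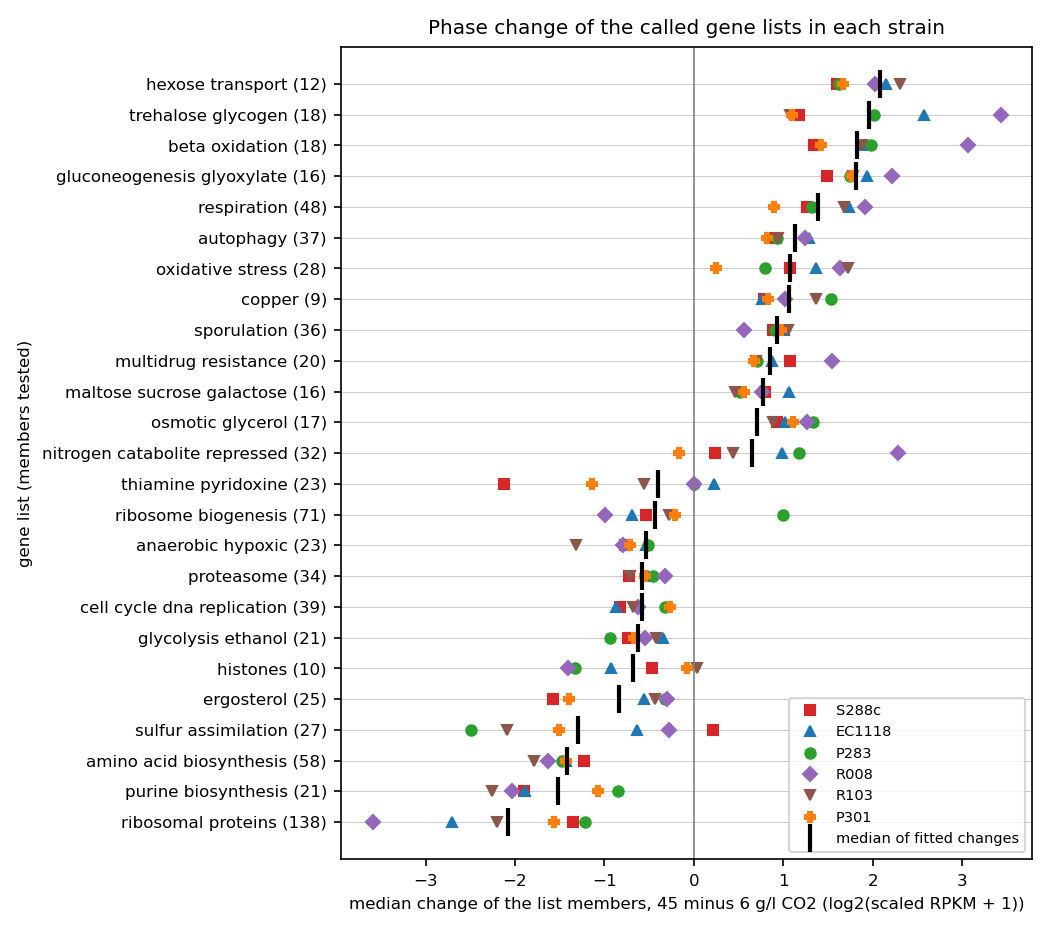
Median change of the tested members of each of the 25 called gene lists (y axis, with the number of members) between 6 and 45 g/l CO2, in log2(scaled RPKM + 1) (x axis), with coloured symbols for the 6 strains, 1 pair of libraries each, and black bars for the median of the fitted changes. Ribosomal protein genes lie lowest, at −2.08, and hexose transporters highest, at 2.08, and the strains lie on both sides of 0 for sulfur assimilation, ribosome biogenesis, nitrogen catabolite repression, thiamine and histones.

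With RPKM as deposited, the median of all genes moved by 0.33 in place of 0.09, and the calls were 2003 upward and 967 downward. Under quantile normalization they were 1326 and 1588, and the glycolysis, ergosterol, thiamine, anaerobic, proteasome, histone and maltose lists were no longer called. The glycolysis list also lost its call with a pseudocount of 0.1.

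Within each strain, 2018 to 2838 genes differed at least 2-fold between its 2 libraries, counts that have no replicate and no test. R008 had the most (1488 higher and 1350 lower at 45 g/l) and P301 the fewest (1082 and 936). S288c had 2476, EC1118 2295, P283 2406 and R103 2783. In all 6 strains, 361 genes were at least 2-fold higher and 299 at least 2-fold lower at 45 g/l. Across genes, which are not independent replicates, the slope of a strain's change on the mean change of the other 5 ran from 0.73 in P301 to 1.22 in R008.

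The second comparison asked how the laboratory strain differs from the vineyard isolates. Mating genes stood highest among the genes not listed at 0: MF(ALPHA)1 (YPL187W, chromosome 16, 193647 to 194144), which encodes the alpha-factor pheromone, had 389 and 109 scaled RPKM in S288c at 6 and 45 g/l and at most 2.74 in the 4 vineyard strains, a log2 difference of 6.87 ± 0.35 (SE, limma, adjusted p = 0.00161). STE3, the receptor for a-factor, had 136 and 35.2 scaled RPKM in S288c and at most 2.59 in the vineyard strains (5.36 ± 0.40, adjusted p = 0.0068). FAR1, which arrests the cycle in response to pheromone, had 161 and 32.8 against at most 2.94 (5.12 ± 0.28, adjusted p = 0.00207). IME4, an mRNA methyltransferase gene needed for sporulation, was lower in S288c, at 0.385 and 0.606 scaled RPKM against 9.09 to 14 in the vineyard strains (−3.03 ± 0.22, adjusted p = 0.00625). In total 127 of 5944 genes differed, 121 higher and 6 lower in S288c, and 886 had an unadjusted p under 0.05.

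Genes listed at 0 made up much of this count. Of the 127 genes, 93 were listed at 0 in both libraries of some strain, 86 in all 4 vineyard strains, and 48 were retrotransposon reading frames. The 93 retrotransposon reading frames of the table summed to 10984 and 22042 scaled RPKM in S288c at 6 and 45 g/l, with 32 and 29 of them listed at 0. They summed to 459 and 1211 in EC1118, to 1777 and 1622 in P301, and to between 5.05 and 33.0 in P283, R008 and R103, where 91 or 92 were listed at 0. In P301, YDR210W-A and YDR261W-A had the same values (400.9 and 341.5), as did YDR210W-B and YDR261W-B (335.5 and 304.7). The P301 sums may therefore hold the same reads more than once. Without the genes listed at 0 in both libraries of a strain, 34 of 5419 differed, 30 higher and 4 lower in S288c, and 24 of these were called in both fits.

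TEF2, a translation elongation factor gene whose near-identical copy TEF1 can take its reads, had 6241 and 1949 scaled RPKM in S288c and 0 to 2 in the vineyard strains. The subtelomeric genes COS6 (395 and 623) and COS4 (40.1 and 208, with the near-identical copy COS1) were listed at 0 in all 8 vineyard libraries. So were YHL050C (146 and 256) and YER138W-A (262 and 332), both with near-identical copies. AAD6, an aryl-alcohol dehydrogenase of the candidate list, had 29.1 and 46.3 scaled RPKM in S288c and was listed at 0 in the other 10 libraries. With S288c set against the other 5 strains, TEF2, COS6 and COS4 were no longer called, and with a pseudocount of 0.1 TEF2 was not.

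Among genes not listed at 0, the amino acid permease gene TAT1 had 304 and 85.5 scaled RPKM in S288c and 2.84 to 11 in the vineyard strains, a log2 difference of 4.67 ± 0.42 (adjusted p = 0.0154). The phosphate transporter gene PHO84 had 132 and 16.4 against at most 2.93 (4.62 ± 0.42, adjusted p = 0.0155), and the pheromone gene MF(ALPHA)2 had 59.7 and 16.9 against at most 1.29 (4.64 ± 0.28, adjusted p = 0.00292). Lower in S288c were VPH2, an assembly factor of the vacuolar ATPase (−1.73 ± 0.21), DIF1, a regulator of ribonucleotide reductase (−1.65 ± 0.17), MDP-1 (−1.69 ± 0.20) and YGR161W-C (−1.64 ± 0.20), with adjusted p from 0.0218 to 0.0453. SOR2, which has a near-identical copy and is listed at 0 in both EC1118 libraries, was lower too (−2.53 ± 0.31, adjusted p = 0.0453), and does not enter the fit without the genes listed at 0. Without the genes listed at 0, VPH2, DIF1, MDP-1 and YGR161W-C were no longer called (adjusted p from 0.0765 to 0.0938). HXT6, a hexose transporter gene with a near-identical copy (−3.74 ± 0.46, adjusted p = 0.00793), and YOL014W (−2.31 ± 0.39, adjusted p = 0.0471) were called there.

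Of 24 genes in the mating list, 11 were higher in S288c and 13 did not pass (19 higher adjusted over the list alone), with a median log2 difference of 2.12 (camera, adjusted p = 2.55e-12, and adjusted p = 0.59 with an estimated correlation). Respiration genes had a median of −0.98 with 0 of 48 past the threshold in limma (also 0 adjusted over the list alone), and the list was called lower (adjusted p = 3.43e-06, and adjusted p = 0.677 with an estimated correlation). Ergosterol genes had a median of −0.91 with 0 of 25 past the threshold (also 0 adjusted over the list alone), and were called lower as well (adjusted p = 0.000169, and adjusted p = 0.677 with an estimated correlation). The thiamine and pyridoxine list was called higher, with 3 of 23 genes higher (also 3 adjusted over the list alone) and a median of 0.97 (adjusted p = 0.000841, and adjusted p = 0.67 with an estimated correlation). Without the genes listed at 0 in both libraries of a strain, the median of this list was 0.63 over 15 genes. The phosphate list was called higher too, with 2 of 19 genes higher (also 2 adjusted over the list alone) and a median of 0.43 (adjusted p = 0.0191, and adjusted p = 0.677 with an estimated correlation). Purine genes had a median of 0.62 with 0 of 21 past the threshold (adjusted p = 0.0108, and adjusted p = 0.677 with an estimated correlation), and proteasome genes a median of −0.42 with 0 of 34 (adjusted p = 0.00049, and adjusted p = 0.677 with an estimated correlation). The aroma list had a median of 0.64 with 2 of 25 higher (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0438, and adjusted p = 0.67 with an estimated correlation). The anaerobic list had a median of −0.43 with 0 of 23 past the threshold (adjusted p = 0.0438, and adjusted p = 0.67 with an estimated correlation), and the cell cycle list one of 0.32 with 0 of 39 (adjusted p = 0.0438, and adjusted p = 0.67 with an estimated correlation). Adjusted over the list alone, the purine, proteasome, anaerobic and cell cycle lists also had 0 genes past the threshold in limma. An unadjusted p under 0.05 was reached by 13 respiration, 6 ergosterol, 3 purine, 4 proteasome, 7 anaerobic and 7 cell cycle genes.

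**Figure D3:**
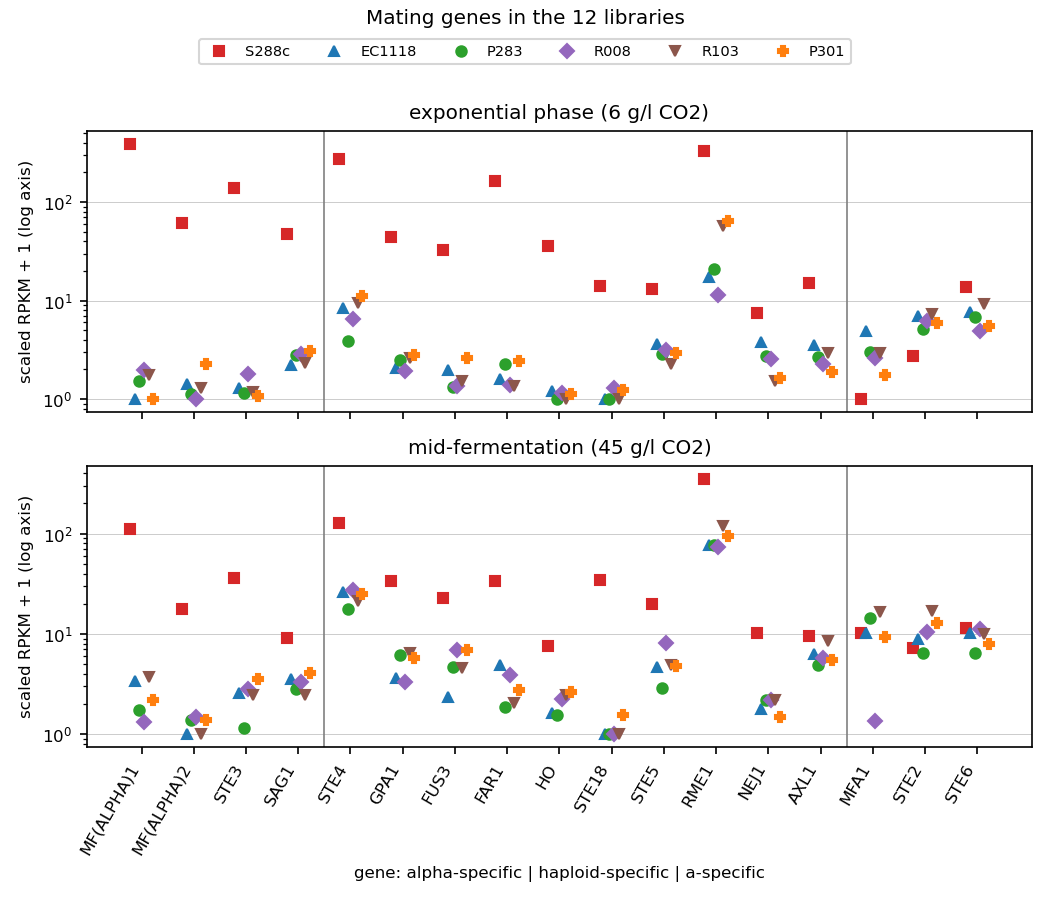
Scaled RPKM + 1 (y axis, log scale) of 17 mating genes (x axis) in the 6 strains at 6 g/l CO2 (upper panel) and 45 g/l CO2 (lower panel), 1 library per symbol, with vertical lines between alpha-specific, haploid-specific and a-specific genes, classes drawn up after the values had been seen. S288c lies far above the other 5 strains for MF(ALPHA)1, at 389 and 109 scaled RPKM, and not for the a-specific genes MFA1 and STE2, while the a-specific STE6 was also highest in S288c, at 12.9 and 10.6 against at most 8.19 and 10.1 in the other strains.

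STE3 was no longer called without R103 (5.36), PHO84 without R008 (4.66) or P301 (4.55), and TAT1 without P283 (4.55), R008 (4.70) or R103 (4.57). STE3 and PHO84 also lost their call with a pseudocount of 0.1 and in the mid-fermentation libraries alone, FAR1 in the mid-fermentation libraries alone, and MF(ALPHA)2 with a pseudocount of 0.1. SOR2 was no longer called without R008 (−2.46), R103 (−2.47) or P301 (−2.51) and under 4 further alternatives. VPH2 lost its call without P283 (−1.79), R008 (−1.67), R103 (−1.75) or P301 (−1.70), and DIF1 without P283 (−1.62), R008 (−1.68), R103 (−1.67) or P301 (−1.65). MDP-1 did so without P283 (−1.62), R008 (−1.70), R103 (−1.72) or P301 (−1.70), and YGR161W-C without P283 (−1.58), R008 (−1.63), R103 (−1.70) or P301 (−1.65). These 4 genes were also not called in the libraries of either phase alone, and each lost its call under further alternatives. HXT6 was called over all genes without P283 (−3.98), with RPKM as deposited, under quantile normalization, with a pseudocount of 5 and under robust empirical Bayes. The anaerobic and cell cycle lists lost their call under quantile normalization, with RPKM as deposited and with a pseudocount of 0.1, the proteasome list under quantile normalization, and the aroma list without the genes listed at 0.

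The third comparison set the wine strain EC1118 against the vineyard isolates. Without the genes listed at 0 in both libraries of a strain, 1 of 5419 differed in limma: IRC7 (YFR055W, chromosome 6, 264191 to 265213), a beta-lyase gene linked to the release of volatile thiols in wine, had 2.05 and 1.37 scaled RPKM in EC1118 at 6 and 45 g/l and 37.1 to 178 in the vineyard strains, a log2 difference of −4.62 ± 0.47 (SE, adjusted p = 0.0321). Over all 5944 genes its adjusted p was 0.0751, so it was not called there, and it overlaps a gene on the opposite strand. Over all genes 52 differed, 36 higher and 16 lower in EC1118, and 49 of them were listed at 0 in both libraries of some strain. An unadjusted p under 0.05 was reached by 247 genes, and by 152 without the genes listed at 0.

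Zeros stood on both sides. Listed at 0 in both EC1118 libraries were DLD3, a lactate dehydrogenase gene (302 to 3649 scaled RPKM in the vineyard strains), the ribosome biogenesis ATPase gene ARB1 (152 to 450) and RPL36B (66.6 to 296). So were YER187W (41.8 to 305), the sphingoid base phosphatase gene YSR3 (73.4 to 220) and IDH1, a subunit of isocitrate dehydrogenase (46.6 to 164). Listed at 0 in all 8 vineyard libraries were COS6 (398 and 1621 scaled RPKM in EC1118), COS4 (134 and 382), YLR464W (64.7 and 105) and YFL066C (36.9 and 73.5), the last 3 with near-identical copies. TEF2 had 630 and 175 scaled RPKM in EC1118. RPL4A, whose copy RPL4B is near-identical, had 302 and 39 scaled RPKM against 0 to 1.93, a call lost without P283 (adjusted p = 0.105), R008 (0.174), R103 (0.154) or P301 (0.136) and under 5 further alternatives. The call of TEF2 was lost without P283 (0.0955), R008 (0.12) or R103 (0.113) and with a pseudocount of 0.1. That of YER187W was lost without P283 (0.104), R008 (0.0684) or P301 (0.116) and under 2 further alternatives, and that of IDH1 without R103 (0.0639) or P301 (0.0753) and in the exponential libraries alone. RPL36B was no longer called in the mid-fermentation libraries alone.

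Lists differed by small amounts. Ribosomal protein genes had a median log2 difference of 0.53 with 1 of 138 higher and 1 lower (the same adjusted over the list alone, adjusted p = 3.47e-10, and adjusted p = 0.588 with an estimated correlation), and ribosome biogenesis genes one of 0.27 with 0 of 71 past the threshold in limma (adjusted p = 0.00119, and adjusted p = 0.588 with an estimated correlation). Sulfur assimilation genes had a median of −0.68 (0 of 27, adjusted p = 1.77e-05, and adjusted p = 0.588 with an estimated correlation) and heat shock genes one of −0.35 (0 of 27, adjusted p = 0.00195, and adjusted p = 0.588 with an estimated correlation). Trehalose and glycogen genes had a median of −0.31 (0 of 18, adjusted p = 0.0014, and adjusted p = 0.66 with an estimated correlation) and beta-oxidation genes one of −0.33 (0 of 18, adjusted p = 0.0141, and adjusted p = 0.588 with an estimated correlation). Respiration genes had a median of −0.29 with 1 of 48 lower, IDH1 (adjusted p = 0.00781, and adjusted p = 0.796 with an estimated correlation). Purine genes lay at 0.48 (0 of 21, adjusted p = 0.0015), amino acid genes at 0.19 (0 of 58, adjusted p = 0.0275), cell cycle genes at 0.17 (0 of 39, adjusted p = 0.0302) and histones at 0.38 (0 of 10, adjusted p = 0.047). The wine and laboratory candidates lay at −0.20 (0 of 17, adjusted p = 0.0364). Each of these last 5 lists had adjusted p = 0.588 with an estimated correlation. Adjusted over the list alone, the counts stayed as given, except for 1 lower candidate gene. In the lists with a count of 0, between 0 and 2 genes had an unadjusted p under 0.05.

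The cell cycle list lost its call under quantile normalization, and the histone and candidate lists with a pseudocount of 0.1.

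The fourth comparison asked whether the change from 6 to 45 g/l itself differed between S288c or EC1118 and the vineyard strains. By gene lists, ribosomal protein genes were called, with a median log2 difference of 0.86 and 0 of 138 past the threshold in limma (camera, adjusted p = 0.000248, and adjusted p = 0.849 with an estimated correlation, which was 0.607). Their median change in S288c, −1.35, lay within the range of the vineyard strains, from −1.22 in P283 to −3.59 in R008. Mating genes changed by −0.57 in S288c and by 0.25 to 1.06 in the vineyard strains, a difference of −1.48 (adjusted p = 2.61e-06, and adjusted p = 0.624 with an estimated correlation). Sulfur assimilation genes changed by 0.21 in S288c and by −0.28 to −2.49 in the vineyard strains, a difference of 1.78 (adjusted p = 0.000618, and adjusted p = 0.849 with an estimated correlation).

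Further lists with a positive or negative difference in the response of S288c were amino acid genes (0.58, adjusted p = 0.00287, and adjusted p = 0.624 with an estimated correlation), ergosterol genes (−0.87, adjusted p = 0.00076, and adjusted p = 0.849 with an estimated correlation) and ribosome biogenesis genes (−0.36, adjusted p = 0.0147, and adjusted p = 0.849 with an estimated correlation). Thiamine genes changed by −2.12 in S288c, a difference of −0.95 (adjusted p = 5.62e-06, and adjusted p = 0.624 with an estimated correlation). Phosphate genes differed by −0.43 (adjusted p = 0.00257, and adjusted p = 0.624 with an estimated correlation), beta-oxidation genes by −0.80 (adjusted p = 0.0166, and adjusted p = 0.849 with an estimated correlation) and seripauperin genes by −1.55 (adjusted p = 0.00772, and adjusted p = 0.666 with an estimated correlation). Without the genes listed at 0 in both libraries of a strain, the thiamine difference was −0.49 over 15 genes. The seripauperin list kept 3 members there and was not tested. The 24 seripauperin genes, near-identical cell wall proteins given as a family, summed to 746 and 805 scaled RPKM in S288c at 6 and 45 g/l, and at 45 g/l to 5124 to 22407 in the other 5 strains. In these 10 lists 0 genes passed over all genes in limma. Adjusted over the list alone, 10 mating genes had a lower and 2 a higher response, 6 seripauperin genes a lower and 2 a higher one, 4 thiamine genes and 1 phosphate gene a lower one, and 0 in the other 6 lists. An unadjusted p under 0.05 was reached by 14 mating, 8 seripauperin, 5 thiamine, 5 amino acid and 4 phosphate genes, and by 1 to 3 in each of the other 5 lists. The beta-oxidation list lost its call with RPKM as deposited and under quantile normalization, and the seripauperin and ribosome biogenesis lists with RPKM as deposited.

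By single genes, 2 of 5944 passed for S288c and 353 had an unadjusted p under 0.05. Both, YER138C and YML039W, are reading frames of Ty elements with near-identical copies, had 153 and 102 scaled RPKM in S288c at 45 g/l and were listed at 0 in the other 11 libraries. Without genes listed at 0 in both libraries of a strain, 0 of 5419 passed in limma (218 at an unadjusted p under 0.05). The smallest p there belonged to YBR141W-A, YMR086C-A and YPL088W. YPL088W, a putative aryl alcohol dehydrogenase gene, had 33.8 and 216 scaled RPKM in S288c at 6 and 45 g/l and 106 to 257 in the vineyard strains.

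For EC1118, 0 of 5944 genes passed in limma and 122 had an unadjusted p under 0.05, and without genes listed at 0 these counts were 0 of 5419 and 64. The smallest p belonged to HSP33, THI12 and PAU12 (adjusted p = 0.126 each), which have near-identical copies and are each listed at 0 in both libraries of at least 3 vineyard strains. Without the genes listed at 0, it belonged to YKL162C-A, YJL043W and the pyruvate decarboxylase gene PDC5, which had 87.4 and 376 scaled RPKM in EC1118. Over the 15 thiamine genes not listed at 0 in both libraries of a strain, the response of EC1118 differed by a median of 0.95. In P283 and R008 the median change of all 23 was 0, the value of any member listed at 0 in both libraries. Thiamine genes changed by 0.23 in EC1118 and by −1.14 to 0 in the vineyard strains, a difference of 0.95 (adjusted p = 7.71e-09, and adjusted p = 0.78 with an estimated correlation), with 0 of 23 past the threshold and 3 higher adjusted over the list alone. The difference was negative for ribosome biogenesis (−0.63, adjusted p = 1.06e-05), ribosomal protein (−0.40, adjusted p = 0.000253) and cell cycle genes (−0.40, adjusted p = 0.0181). These 3 lists had adjusted p = 0.92 each with an estimated correlation and 0 genes past the threshold, also adjusted over the list alone. An unadjusted p under 0.05 was reached by 4 thiamine, 2 ribosomal protein, 2 cell cycle and 0 ribosome biogenesis genes.

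In simulated data these tests recovered 10% (S288c) and 4% (EC1118) of genes with an 8-fold difference in response, so most differences of that size were not detectable. The 2 calls for S288c were 0 without P283, R008, R103 or P301.

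The fifth comparison asked which genes differ between the strains at all. HHT2, a histone H3 gene, had 1.24 and 1.47 scaled RPKM in R103 and 416 to 1665 in the other strains. IRC21 had 0.104 and 0 in P301 and 18.7 to 46.3 elsewhere, and YDR278C 0 and 0.376 in P301. Of 5944 genes, 545 had a strain effect (limma, moderated F test, 1022 at an unadjusted p under 0.05), and 437 of these were listed at 0 in both libraries of some strain. Without such genes 39 of 5419 had one, and all 39 were among the 545. Only genes at exactly 0 in both libraries of a strain were left out, so near-zero values such as those of HHT2 and IRC21 stayed in.

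The largest differences of a strain from the other 5 were those of listed zeros. Besides TDH1 and OLE1 in P283 and DLD3 in EC1118, MET22, a phosphatase gene of sulfur assimilation, and RPL1B were listed at 0 in R008 (161 to 3249 and 39.1 to 14681 scaled RPKM in the other strains). The squalene epoxidase gene ERG1 and RPS8A were listed at 0 in R103 (476 to 4399 and 405 to 9148 elsewhere). TDH2 was listed at 0 in P301 and P283 (316 to 15737 elsewhere), and RPS22A in P301 (58 to 4148 elsewhere). RPL1B, RPS8A and TDH2 have near-identical copies. COS1 had 422 and 507 scaled RPKM in S288c and at most 10.9 elsewhere.

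Without listed zeros, MF(ALPHA)1 and STE3 differed most in S288c (6.86 and 5.34 on the log2 scale from the other 5 strains) and IRC7 in EC1118 (−4.79). RPL11A, which has a near-identical copy, had 1936 and 656 scaled RPKM in S288c, 5172 and 870 in EC1118 and 6616 and 1049 in P283, against 6.09 to 304 in R008, R103 and P301. RPS4B, likewise with a copy, had 4.04 and 2.64 in R008, and RPL42B 14.1 and 16 in R103.

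The candidates known to vary between wine and laboratory yeasts were given in any case. SSU1, the sulfite pump gene, had 64.8 and 45.8 scaled RPKM in S288c at 6 and 45 g/l and 268 to 3906 in the other strains, with R103 and R008 highest, and the difference of S288c from the vineyard strains, −4.45 ± 1.04, did not pass (adjusted p = 0.195). CUP1-1, a metallothionein gene with a near-identical copy, had 1027 and 2963 scaled RPKM in P283, 2547 and 5137 in R008 and 1349 and 19148 in R103, and was listed at 0 in S288c, EC1118 and P301. HAP1, the haem-responsive activator gene, had 65.8 and 156 scaled RPKM in S288c and 20.4 to 88.2 in the vineyard strains, a difference of 1.28 ± 0.34 that did not pass (adjusted p = 0.23). ENA1, a sodium pump gene with a near-identical copy, was listed at 0 in P283, R008 and P301 and had 10.7 to 40.4 scaled RPKM in S288c, EC1118 and R103. AQY1, an aquaporin gene, had 0.487 and 10.5 scaled RPKM in S288c and at most 1.97 in the vineyard strains (1.68 ± 0.40, adjusted p = 0.199). FLO8, AQY2, MKT1, SAL1, FZF1, RIM15, ADH7, HXT3, ENA5 and CUP1-2 were not called for S288c (adjusted p from 0.567 to 0.916) or EC1118. Another 8 of the 25 candidates, MUC1, ENA2, HXT13, HXT15 and 4 ASP3 copies, had a mean below 1 RPKM and were not tested.

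With the vineyard strains alone, 272 genes had a strain effect. Leaving out 1 strain at a time gave 365 to 533 genes, the fewest without S288c.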

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

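Of the tests in this part, those on near-identical copies, essential genes, neighbouring genes, a swap or a later point of the P301 libraries, a mixed culture and the cell type of S288c were chosen only after the result was seen.

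Mating genes set S288c apart from the vineyard strains: 4 of 4 alpha-specific genes were higher in S288c, with a median log2 difference of 5.00, and 6 of 10 haploid-specific genes were. With RPKM as deposited, the median of the alpha-specific genes was still 4.79. The scale factors, 0.807 to 1.28, were too small for this check to come out otherwise, and their size argues against scaling as the whole cause. A culture that holds cells of both mating types would raise the a-specific genes too, but the 3 of 7 that could be tested had a median of −0.44 (−0.87 to 0.76, the highest being STE6). The haploid-specific genes had a median of 3.31 (3.06 with RPKM as deposited and 2.86 under quantile normalization). This would go with S288c cells of the alpha mating type beside diploid cells of the other strains. MATALPHA2 and its copy HMLALPHA2 were listed at 0 in both S288c libraries and MATALPHA1 in all 12. These genes have near-identical copies, so their zeros do not show a lack of expression. MATALPHA2 had 27.2 and 125 scaled RPKM in P283 and 12.1 and 47.45 in P301, and was listed at 0 in EC1118, R008 and R103. Its copy HMLALPHA2 had 6.36 and 8.79 in EC1118 and 0.382 and 3 in R103, and was listed at 0 in P283, R008 and P301. HMLALPHA1 had 0 and 9.4 in EC1118 and 0 and 2.94 in R103, and was listed at 0 elsewhere. HMRA2, which also has a near-identical copy, had 48.7 and 167 in R008 and was listed at 0 elsewhere. The a-gene HMRA1 had 1.56 and 0 scaled RPKM in S288c, 21.3 to 130 in P283, R008 and P301, and 0 in EC1118 and R103. P283 and P301 thus had values for both an alpha and an a gene, which would go with diploid cells in these strains. For S288c the zeros decide nothing, ploidy was not measured, and the cell type of the strains stays open, as does a difference in origin.

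Genes listed at 0 in both libraries of a strain while expressed elsewhere were seen in all 6 strains. Reads shared between near-identical copies are argued against as the cause for most of the genes listed at 0 in 1 strain alone, because 20 of these 218 genes, 9.2%, had such a copy, while they could be the cause for many of the 131 listed at 0 in several strains, of which 90, or 68.7%, had one. Absence of the gene from the strain is argued against for at least 4 essential genes, CBF5 and NOP58 in P283 and RPB8 and HTS1 in R103, from an incomplete list (GLC7, outside it, was listed at 0 in P283 and had 371 to 921 scaled RPKM elsewhere), and stays open for the others. Of the 137 genes of that list with a mean of at least 10 RPKM, 2.92% were listed at 0 in both libraries of a strain. This share was lower than the 6.8% of all 4897 genes at that level. Missing stretches of neighbouring genes could be the cause for some, since 15 pairs of neighbours were found against a median of 2 and a highest of 9 in 10000 random draws (one-sided permutation p = 1e-04, the smallest these draws can give), but 13.6% of the genes, 27 of 199, lay in such a pair. The 199 are those of the 218 that are not dubious reading frames and had a mean of at least 10 RPKM over all libraries. How the authors' counting treated a strain's differences from the reference sequence, and a limit or loss in the making of the table, were not tested, and the strains' own genomes stay among the open explanations. YKL222C was left out for conflicting lines. For P283 at 6 g/l, some of these lines gave 4.68 RPKM and others 0, with the values of the other strains equal.

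The exponential library of P301 scored 0.26 on an axis from the mean exponential library (0) to the mean mid-fermentation library (1) of the other 5 strains. The exponential libraries of those strains scored −0.15 to 0.16 (SD 0.13). Each was scored on its own axis, built from the 5 strains other than itself and thus with P301 among them, so the scores compared lie on unlike axes. A swap of the P301 libraries is argued against by its mid-fermentation library, which scored 0.99, that is 0.73 above. Admixture of P301 mid-fermentation RNA stays open. The share of 11% that the 402 most risen genes give would lower the 281 most fallen genes by 0.14 on the log2 scale, 32.1% (95% resampling interval of genes 24.6% to 47.9%) of their observed median drop of 0.42. Taken alone, this share would account for only part of the drop. The test cannot decide, because it takes the mean exponential library of the other strains as the starting level of P301. The interval resamples genes and leaves out the spread between strains. Whether the library was taken at a later point of the shared course cannot be told apart from the spread between strains, because 0.26 lies above the highest other score by less than the SD of those scores. A difference between strains in the pace of fermentation was not tested.

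The 2891 genes that changed with phase were set against the 32 ways to swap the phases within strains: 1 of them, the real one, gave as many, and the highest of the others gave 0 in limma, so chance can be excluded at 1 in 32, the smallest share these swaps can give.

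Strains far from the other 5 were sought in 303 sets of 6 values, and 73 sets were found, in 46 genes and 1 library measure, where chance gives about 1 in 20. The values below are the gap to the nearest strain as a share of the range of the 6 strains, and the threshold is Dixon's 95% critical value for 6 samples. For genes, gap and range were taken on log2(scaled RPKM + 1), and for library measures on the plain values. Where a strain is listed at 0, the value therefore depends on the pseudocount. In the sets of gene values S288c was highest in 19 and lowest in 10, EC1118 in 5 and 13, P283 in 1 and 4, R008 in 1 and 3, R103 in 0 and 9, and P301 in 2 and 5, and in the library measure R008 was lowest. Many of these genes were named because a strain differed, so their number is no evidence of its own.

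Among genes named for the phase, P301 was highest at 6 g/l for PDC6 (0.63) and HXT2 (0.64). At 45 g/l R103 was lowest for HXT4 (0.64), R008 highest for IGD1 (0.66), S288c highest for RME1 (0.68) and S288c lowest for CYC7 (0.83). At 6 g/l S288c was lowest for STE2 (0.64). For FLO8, named as a gene of the candidate list and not for the phase, P283 was highest at 6 g/l (0.69).

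S288c was highest at 6 and 45 g/l for MF(ALPHA)1 (0.89 and 0.76), MF(ALPHA)2 (0.80 and 0.86), STE3 (0.89 and 0.67), FAR1 (0.88 and 0.67) and TAT1 (0.85 and 0.74). It was highest at 6 g/l for PHO84 (0.74) and COS1 (0.77). For YER138W-A, YHL050C and AAD6 the value was 1 at both points, with the other 5 strains listed at 0. S288c was lowest at both points for IME4 (0.88 and 0.85) and VPH2 (0.69 and 0.69), and at 6 g/l for MDP-1 (0.65), YOL014W (0.68), YBR141W-A (0.65) and YPL088W (0.73).

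EC1118 was lowest at 6 and 45 g/l for DLD3 (0.85 and 0.88), ARB1 (0.89 and 0.82), RPL36B (0.92 and 0.76), YSR3 (0.87 and 0.88) and IDH1 (0.76 and 0.87), all listed at 0 there, and for IRC7 (0.71 and 0.76). It was lowest at 45 g/l for YER187W (0.68). It was highest at both points for YFL066C (1 and 1), with the others listed at 0, and at 6 g/l for YLR464W (0.67), PAU12 (0.68) and YKL162C-A (0.79).

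P283 was lowest at 6 and 45 g/l for TDH1 (0.88 and 0.94) and OLE1 (0.92 and 0.95), and R008 for MET22 (0.72 and 0.85), with RPL1B at 6 g/l (0.64). R103 was lowest at both points for ERG1 (0.91 and 0.79), RPS8A (0.82 and 0.85), HHT2 (0.82 and 0.90) and RPL42B (0.64 and 0.71). P301 was lowest at both points for RPS22A (0.79 and 0.77) and IRC21 (0.81 and 0.85), and at 45 g/l for YDR278C (0.66). At 45 g/l R008 also had the fewest genes at 10 RPKM or more (0.63), 4542 against 4772 to 4908 in the other strains.

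The phase response of S288c differed from that of the vineyard strains for YER138C (a fitted 7.26) and YML039W (6.69), which depend on the pseudocount because 11 libraries are listed at 0. With the preset correlation in camera it was called different, by a median of 0.86 for ribosomal protein, −0.36 for ribosome biogenesis, 0.58 for amino acid, 1.78 for sulfur assimilation, −0.87 for ergosterol, −0.95 for thiamine, −0.43 for phosphate, −1.48 for mating, −1.55 for seripauperin and −0.80 for beta-oxidation genes. For EC1118 the response was called different by −0.40 for ribosomal protein, −0.63 for ribosome biogenesis, 0.95 for thiamine and −0.40 for cell cycle genes. The median change of S288c lay within or at the edge of the vineyard range for ribosomal protein, ribosome biogenesis, phosphate and seripauperin genes. That of EC1118 lay within it for ribosomal protein and ribosome biogenesis genes. In camera, 0 of these 14 list differences held with an estimated correlation, where 2 of the S288c and 1 of the EC1118 lists had an unadjusted p under 0.05.

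Outside the comparisons, the line of the table that names no gene held 0.365% of the summed RPKM of S288c at 45 g/l. One of the conflicting lines of YPL250W-A gave 1298 RPKM in EC1118 at 6 g/l, and another gave 0.28. The lines of this gene differed in the EC1118 values alone, and those of YKL222C and YKL223W in the P283 values alone.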

How the results depend on the processing

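Leaving out the genes listed at 0 in both libraries of a strain was chosen only after the result was seen, as were the 2-fold counts within strains under other settings. No named gene or called list changed direction under the alternatives run for it. For the alternatives below the cause was not tested, except that fewer strains or genes enter where the name says so.

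With the vineyard strains only, 1600 genes changed with phase in place of 2891, and 272 had a strain effect in place of 545. Leaving out 1 strain gave 2392 to 2855 and 365 to 533. Without the strain block 2590 genes changed with phase, and ADH4, ZRT1, RME1 and BIO2 were no longer called. Of 78 genes named for the phase, 73 kept their call state under quantile normalization and 77 with RPKM as deposited.

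For S288c against the vineyard strains (127 genes), no filter gave 221, a mean of at least 10 RPKM 62, and leaving out the genes listed at 0 gave 34. Leaving out 1 other strain gave 113 to 128. For EC1118 (52 genes), a mean of at least 10 RPKM gave 30 and leaving out the genes listed at 0 gave 1. Leaving out 1 other strain gave 46 to 52. The strain effect fell to 39 genes without the genes listed at 0.

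For the response of S288c (2 genes), quantile normalization gave 4, a pseudocount of 0.1 gave 6, no filter 19, a mean of at least 10 RPKM 1, robust empirical Bayes 5, S288c against the other 5 strains 16, and leaving out the genes listed at 0 gave 0. Leaving out 1 other strain gave 0 to 2, with 0 without P283, R008, R103 or P301. The response of EC1118 gave 0 in limma under each alternative, where 122 genes had an unadjusted p under 0.05 before any change.

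Of the lists, camera with an estimated correlation called 0 for the phase (in place of 25), 0 for S288c (10), 0 for EC1118 (12), 0 for the response of S288c (10) and 0 for that of EC1118 (4), with 9, 1, 0, 2 and 1 at an unadjusted p under 0.05. Leaving out the genes listed at 0 gave 17 lists for EC1118 and 7 for the response of EC1118. The counts of 2-fold genes within strains stayed within 1.5 times under each of 4 settings. Depth is unknown and limits low values to an extent that could not be computed.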

Other observations

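The tests on HAP1 targets in this part were chosen only after the result was seen, and the restriction to 10 targets was made when the values of all 15 had been seen.

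HAP1 is an activator of genes of respiration and sterol synthesis that responds to haem, and strains derived from S288c are known to carry a Ty1 insertion in it. Its targets lay lower in S288c than in the vineyard strains: CYC7 had 6.18 and 272 scaled RPKM in S288c at 6 and 45 g/l and 12.9 to 2536 in the vineyard strains, ERG5 72.9 and 45.5 against 209 to 1384, and CYB5 91.6 and 41.2 against 208 to 2574. These had the largest differences among the 15 targets, while QCR2 (a log2 difference of −0.16) and YHB1 (−0.25) had the smallest. Of 15 targets, 15 had a negative difference, with a median log2 of −1.86, but 0 passed the threshold in limma and 5 had an unadjusted p under 0.05. A less active HAP1 allele in S288c, which may lower these genes, and a lower level of all genes of respiration and ergosterol synthesis cannot be told apart here. The 10 targets other than the 5 noticed first had a median of −1.35 (−1.58 with RPKM as deposited and −1.54 under quantile normalization), and the other 65 genes of respiration and ergosterol synthesis had one of −0.76. Random lists matched on expression had a median as low in a share of 1e-04, and random lists of those 65 genes in a share of 0.0052, but neither share decides, because the targets were chosen when their values had been seen and genes of 1 pathway vary together, which random lists do not copy. HAP1 transcripts themselves had 65.8 and 156 scaled RPKM in S288c against 20.4 to 88.2 in the vineyard strains, and both explanations stay open.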
